A study of Homo sapiens with 11 samples.

How the data were processed

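Gene expression was measured by RNA-seq of total RNA from 2 cell lines, extracted with a silica-column kit and sequenced on Illumina machines per the labels' protocols. The 11 libraries cover MDA-MB231 and U2OS cells given DMSO or 8 h of doxorubicin, etoposide, MMS or paclitaxel, with 1 library per line and treatment except 2 MDA-MB231 DMSO libraries. No duration is given for DMSO beyond the 8hr in the title of MDA-MB231 DMSO replicate 2. The authors deposited, for each library, a table of whole-number read counts per gene symbol (23228 genes) with 5 summary rows. Base calls were made with CASAVA 1.8.2, reads were aligned with TopHat2 2.0.8b and counted with HTSeq (version not given), per the submitters' processing notes. Those notes name the human build hg19 and the mouse build mm9, so hg19 was taken for these human lines, and no coordinates are printed. The selection of RNA species, the read length and the strand setting of the counting are not given in the sources used here, so reads of overlapping antisense genes cannot be told apart. Reads shared by near-identical genes go uncounted or are split, which makes histone, ribosomal protein and other multi-copy genes uncertain.

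The summary rows held reads aligned to several places (28.4% to 37.5% of all reads tabulated per library) and reads outside genes (7.16% to 9.7%), and stayed out of library sizes and tests. Counts assigned to genes ranged from 16774156 to 31588683 per library. Of 9 pairs compared (each drug library with its DMSO library, and the 2 MDA-MB231 DMSO libraries), none agreed within sampling noise. The chi-square statistic per degree of freedom was lowest, at 8.04, for U2OS paclitaxel against U2OS DMSO, and 28.1 for the 2 MDA-MB231 DMSO libraries.

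The mean response over both lines was fitted in R 4.3.3 with edgeR 4.0.16 (robust quasi-likelihood, TMM normalization, filterByExpr, 15888 genes tested). All 11 libraries entered 1 fit with a term per drug and a block of 3 levels: U2OS, MDA-MB231 libraries with no time in their titles, and MDA-MB231 libraries whose titles end in 8hr, each level with its own DMSO library. The pairing comes from the cell line, and 4 residual degrees of freedom were left. The common biological coefficient of variation was 0.213. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 per contrast. A term for treated U2OS cells, added to the same model with 3 residual degrees of freedom, tested whether the mean response over the 4 drugs differed between lines. SE values are the log2 fold change divided by the square root of the F statistic.

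Within a line, log2 ratios of TMM-scaled CPM were taken against the DMSO library of the same level, with 0.5 added to each CPM, and genes were counted at 2-fold or more where the larger CPM was at least 5. The added 0.5 pulls ratios of low genes toward 0, so a ratio can lie outside its interval. Intervals are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only. The 25 gene lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry, adjusted over 100 list and drug pairs, over 75 for the contrasts of MMS with other drugs and over 25 for the line term. No camera call held with an estimated correlation. Single-library list medians were placed among 10000 random lists matched on mean expression. The design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined.

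Genes named are the 8 highest and 8 lowest called fold changes per drug with the same sign in both lines and a larger CPM of at least 5 in each line, 5 and 5 for each contrast of MMS with another drug, and 8 and 8 called genes for the line term. To these come the 4 highest and 4 lowest ratios per line and drug with a larger CPM of at least 10, up to 4 members per list described, and CDKN1A, MDM2, ATF3, DDIT3, HMOX1, IL8, IL6, FOS, MYC and TUBB2A. Small RNAs, antisense genes, pseudogenes and placeholder symbols were counted but not named. A few of the genes so selected, and 1 explanation weighed for a difference between the lines, are not reported here. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, other filters, a block for line alone, no block, smaller sets of libraries, leaving out each library, and for single-line values total-count scaling, other minimums, other offsets and the other MDA-MB231 DMSO library. With 2 libraries per drug, other groupings of the samples were not counted, and no test for a stray library was run.

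The fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. No other gene responded to a drug in these counts, unlike in the real libraries. The doxorubicin contrast recovered 30% and 70% with 7 false calls (15671 genes), etoposide 30% and 69% with 19 (15650 genes), MMS 24% and 70% with 18 (15633 genes) and paclitaxel 35% and 72% with 12 (15646 genes). MMS against doxorubicin recovered 14% and 61% with 6 false calls (15665 genes), against etoposide 14% and 66% with 9 (15644 genes) and against paclitaxel 18% and 70% with 20 (15668 genes), and the line term 4% and 48% with 10 (15634 genes). Genomic spans, transcript lengths and GC content were taken by symbol from a GRCh38 gene annotation, matching 13861 of 15888 tested genes (87.2%).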

Results

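Gene-level read counts were analysed for 11 RNA-seq libraries of 2 human cancer cell lines. MDA-MB231 is a basal breast cancer line and U2OS is an osteosarcoma line. Cells were exposed for 8 h to doxorubicin (1 µM), etoposide (20 µM), paclitaxel (0.2 µM) or methyl methanesulfonate (MMS, 40 µg/mL), or received the vehicle DMSO. Doxorubicin intercalates into DNA and poisons topoisomerase II, etoposide poisons topoisomerase II, MMS methylates DNA bases, and paclitaxel stabilises microtubules. Each drug had 1 library per line. U2OS had 1 DMSO library and MDA-MB231 had 2, of which replicate 1 carries the same title form as the doxorubicin, etoposide and paclitaxel libraries and replicate 2 the same form as the MMS library. Replicate 2 is described as untreated although its treatment label is DMSO.

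The counts assigned to genes came to 18959126 for U2OS with DMSO, 24490063 with doxorubicin, 31588683 with etoposide, 23783285 with MMS and 22213736 with paclitaxel. For MDA-MB231 they came to 25506368 and 16774156 for DMSO replicates 1 and 2, 23260228 with doxorubicin, 29371451 with etoposide, 26448212 with MMS and 28168939 with paclitaxel. A drug response was tested as the mean change over both lines, with the lines as the 2 replicates of each drug (edgeR quasi-likelihood, Benjamini-Hochberg adjusted, 15888 genes). A gene can be called without having changed in each line. Fold changes from this test are log2 values ± SE with n = 2 libraries per drug. Values within 1 line compare 2 libraries, have no replicate check, and are given as log2 ratios of CPM, read counts scaled to library size. Nothing in the labels says that libraries came from separate cultures. The p-values rest on the spread left after block and drug, which is how far the 2 lines disagree in their drug responses. Part of that spread may be technical, and it holds no replication within a line.

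**Figure D1:**
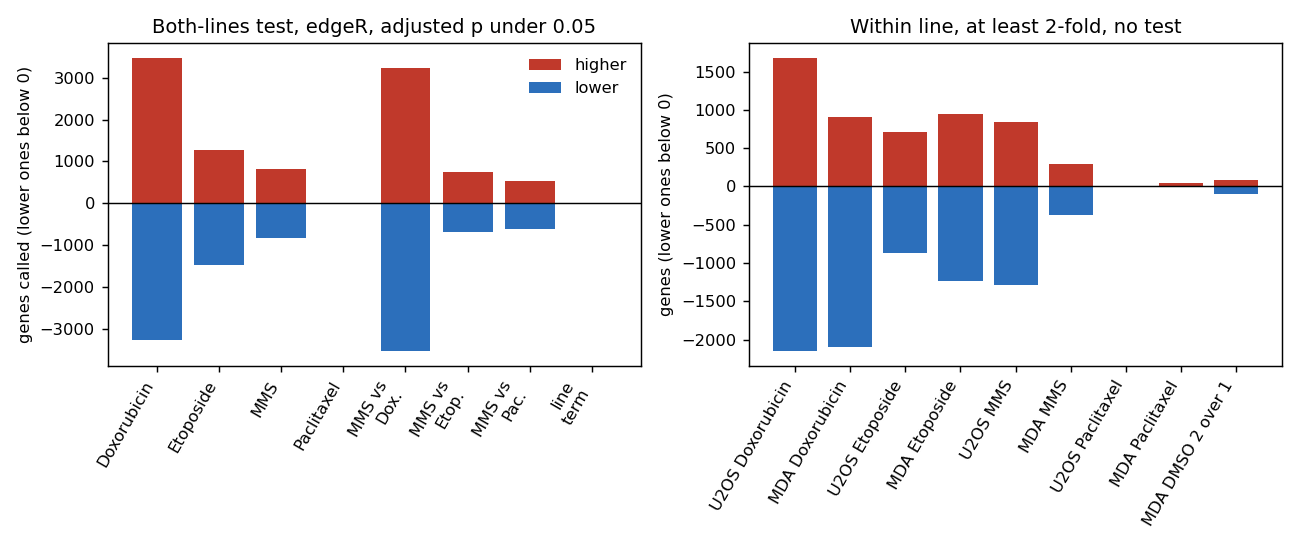
Numbers of genes higher (red) and lower (blue, drawn below 0) per comparison. Left, genes called by edgeR for the mean change over both lines, with 6748 for doxorubicin, 2734 for etoposide, 1651 for MMS and 0 for paclitaxel, the contrasts of MMS with each other drug, and the term for a different response in U2OS (line term). Right, genes at least 2-fold apart between a drug library and its DMSO library, untested, beside the 193 genes that separated the 2 MDA-MB231 DMSO libraries.

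The response to MMS asks what an alkylating agent does beside the classical chemotherapeutics. MMS raised stress-response genes in both lines. ATF3, a stress-induced transcription factor, rose by 4.64 ± 0.54 log2 units (edgeR adjusted p = 0.0053), from 15.3 to 435 CPM in U2OS and from 6.81 to 89.9 CPM in MDA-MB231. HMOX1, the haem-degrading oxygenase, rose by 3.83 ± 0.27 (edgeR adjusted p = 0.00107), from 40.7 to 648 CPM in U2OS and from 12.8 to 133 CPM in MDA-MB231. CHAC1, which degrades glutathione, rose by 3.92 ± 0.33, and DDIT3, the CHOP transcription factor, by 3.28 ± 0.37. Among the genes that fell were RUNX2, the osteoblast transcription factor (-3.13 ± 0.43), NOG, an antagonist of bone morphogenetic proteins (-3.26 ± 0.43), and the pseudokinase gene TRIB2 (-3.46 ± 0.40).

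Integrated stress response genes were the group most uniformly raised by MMS among the 25 lists, as 30 of 33 rose, 0 fell and 3 were not called (32 up and 0 down adjusted over the list alone, camera adjusted p = 3.09e-49, adjusted p = 0.343 with an estimated correlation). Their median log2 fold change was 1.77. Besides ATF3 and CHAC1, the members with the highest values were CTH, a cysteine-synthesis enzyme (3.52 ± 0.53), and ALDH1L2, a mitochondrial folate enzyme (3.31 ± 0.71). Of the NRF2 targets, which respond to oxidants and electrophiles, 18 of 31 rose, 0 fell and 13 were not called (20 up and 0 down adjusted over the list alone, camera adjusted p = 2.41e-27, adjusted p = 0.297 with an estimated correlation). OSGIN1 (3.45 ± 0.37), the cystine transporter gene SLC7A11 (3.11 ± 0.22) and TRIM16L (2.49 ± 0.35, a near copy of part of TRIM16) led that list after HMOX1. Of the ER chaperone list, 7 of 24 rose, 0 fell and 17 were not called (12 up and 0 down adjusted over the list alone, camera adjusted p = 3.02e-08, adjusted p = 0.51 with an estimated correlation). XBP1 (2.08 ± 0.16) and HERPUD1 (1.94 ± 0.23) led it. In the heat shock list 3 of 26 rose, 0 fell and 23 were not called (3 up and 0 down adjusted over the list alone, camera adjusted p = 0.00488, adjusted p = 0.546 with an estimated correlation). HSPA6 was at 3.71 ± 0.71 (2 to 180 reads in MDA-MB231) and ZFAND2A at 1.94 ± 0.25.

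Of the immediate early genes, which growth and stress signals induce within minutes, 10 of 34 rose, 0 fell and 24 were not called after MMS (12 up and 1 down adjusted over the list alone, camera adjusted p = 2.55e-07, adjusted p = 0.417 with an estimated correlation). FOS rose by 3.61 ± 0.36, EGR1 by 3.53 ± 0.67 and ARC by 4.42 ± 0.97. Of the p53 targets, 10 of 42 rose, 0 fell and 32 were not called (13 up and 0 down adjusted over the list alone, camera adjusted p = 9.47e-06, adjusted p = 0.51 with an estimated correlation). GDF15 rose by 3.10 ± 0.58, GADD45A by 2.5 ± 0.28 and CDKN1A, the p21 cell cycle inhibitor, by 1.8 ± 0.46 (a call lost in 12 of 20 alternatives, with adjusted p up to 0.70). MDM2, a ubiquitin ligase gene, rose by 0.86 ± 0.18 (0.43 to 1.39 over 20 alternatives, a call lost in 5). In the short-lived transcript list 14 of 35 rose, 1 fell and 20 were not called (15 up and 4 down adjusted over the list alone, camera adjusted p = 1.65e-07, adjusted p = 0.343 with an estimated correlation). This list is not separate evidence, since 21 of its 35 genes also belong to other lists, as do 11 of the 34 immediate early genes. In the G1/S list of E2F targets 7 of 49 rose, 2 fell and 40 were not called (7 up and 2 down adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.686 with an estimated correlation). CCNE2, a cyclin E gene, rose by 1.08 ± 0.16. IL8, the neutrophil chemokine CXCL8, rose by 1.88 ± 0.23 (0.55 to 2.27 over 20 alternatives, a call lost in 3). IL6 was at 0.47 ± 0.30 and MYC at -0.16 ± 0.32, neither called.

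Genes of the G2 and M phases were lower after MMS, where 0 of 41 rose, 13 fell and 28 were not called (0 up and 18 down adjusted over the list alone, camera adjusted p = 8.27e-11, adjusted p = 0.56 with an estimated correlation). The mitotic kinesin gene KIF20A was at -1.59 ± 0.25 and ANLN, which acts in cytokinesis, at -1.37 ± 0.22. Very long genes, listed for their genomic size, gave the same direction, as 1 of 59 rose, 22 fell and 36 were not called (1 up and 33 down adjusted over the list alone, camera adjusted p = 3.44e-13, adjusted p = 0.51 with an estimated correlation). MAML2, a Notch coactivator, stood at -2.84 ± 0.37 and TCF4 at -2.73 ± 0.50. Of the osteoblast and mesenchymal markers, 0 of 15 rose, 4 fell and 11 were not called (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.000674, adjusted p = 0.51 with an estimated correlation). The cadherin gene CDH11 (-2.17 ± 0.36) was the lowest of them after RUNX2. Further genes among those with the lowest values were ZNF608 (-3.83 ± 0.48), the zinc-sensing receptor gene GPR39 (-3.33 ± 0.41), PDE7B, a cyclic nucleotide phosphodiesterase (-3.20 ± 0.39), and PRR16 (-3.13 ± 0.73). The PRR16 value ran from -5.66 to -1.68 over 20 alternatives, with the call lost in 6.

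In all, 831 genes rose and 820 fell after MMS at adjusted p under 0.05, and 1026 of these 1651 changed by at least 2-fold. The count depended on the libraries in the fit. Without MDA-MB231 MMS or MDA-MB231 DMSO replicate 2, the MMS effect came from U2OS alone. Without U2OS MMS it came from a single pair of MDA-MB231 libraries. Such fits cannot check a response common to both lines, and they cannot say which line the calls lean on. The count was 218 without U2OS DMSO and 481 without MDA-MB231 DMSO replicate 1. It was 973 and 972 without the U2OS or MDA-MB231 paclitaxel library, and 2537 and 2510 without the U2OS or MDA-MB231 doxorubicin library. With only the MMS libraries and their DMSO libraries in the fit it was 641, with DESeq2 2903, and with no block for line 0. Within the lines, 2135 genes differed by at least 2-fold between the U2OS libraries (842 higher, 1293 lower) and 659 between the MDA-MB231 libraries (292 higher, 367 lower).

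**Figure D2:**
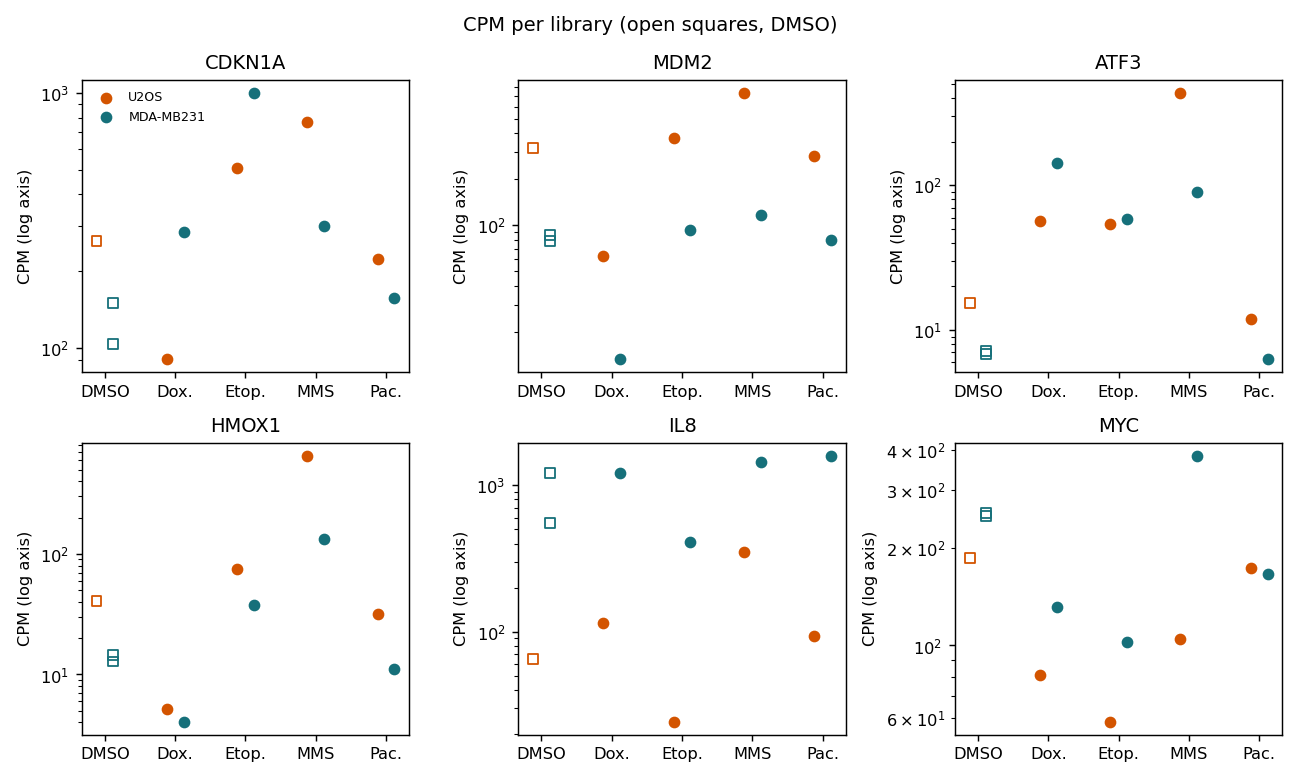
CPM on a log axis in each library for 6 genes, U2OS in orange and MDA-MB231 in teal, with DMSO libraries as open squares and 1 point per library (no replicates of a drug within a line). HMOX1 reached 648 CPM in U2OS and 133 CPM in MDA-MB231 with MMS, and MDM2 lay at 62.9 and 13.4 CPM with doxorubicin.

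Doxorubicin gave the most changed genes of the 4 drugs. Immediate early transcription factors were among the highest, with EGR2 up by 8.12 ± 0.97 and FOSB by 7.63 ± 0.47 log2 units (edgeR adjusted p = 0.000509 and 0.000117), FOSB going from 0.97 to 206 CPM in U2OS and from 1.38 to 387 CPM in MDA-MB231. MDM2 fell (-2.56 ± 0.21, edgeR adjusted p = 0.000152), from 321 to 62.9 CPM in U2OS and from 78.9 to 13.4 CPM in MDA-MB231. Ribosomal protein genes were higher nearly throughout, and genes of mitosis and of homologous recombination were mostly lower.

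Of the ribosomal protein genes, 68 of 73 rose, 0 fell and 5 were not called (69 up and 0 down adjusted over the list alone, camera adjusted p = 3.66e-19, adjusted p = 0.343 with an estimated correlation), with a median of 0.85. RPS10 (1.84 ± 0.27) and RPS15 (1.38 ± 0.17) had the highest values, and many of these genes share sequence with processed pseudogenes, so their counts are uncertain. Of the replication-dependent histone genes, 16 of 29 rose, 0 fell and 13 were not called (19 up and 0 down adjusted over the list alone, camera adjusted p = 1.51e-05, adjusted p = 0.417 with an estimated correlation). HIST1H2BB rose by 4.61 ± 1.04 and HIST1H4I by 3.99 ± 0.98. Histone genes are a family of near-identical copies whose reads can be split or lost in counting. In the same libraries, reads aligned to several places took 37.5% in U2OS and 34.4% in MDA-MB231, against 32.7% and 30% with DMSO. The 20 most abundant genes took 8.07% and 6.33% of gene counts against 5.32% and 4.8%. In the ER chaperone list 15 of 24 rose, 2 fell and 7 were not called (15 up and 2 down adjusted over the list alone, camera adjusted p = 0.00846, adjusted p = 0.746 with an estimated correlation). ERN1 rose by 1.45 ± 0.29, and HERPUD1 fell (-3.15 ± 0.27). Among 9 markers of blood and immune cells, which neither line is known for, 5 of 9 rose, 0 fell and 4 were not called (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.068, adjusted p = 0.51 with an estimated correlation). ITGAM had the highest value (5.6 ± 1.08), at 1 to 37 reads in U2OS and 0 to 59 in MDA-MB231. Fitted folds of genes with 3 or fewer reads in a library depend on the prior count, as for HIST1H2BB (0 to 18 reads in U2OS) and HIST1H4I (3 to 19 in U2OS, 0 to 22 in MDA-MB231).

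Of the G2 and M phase genes, 1 of 41 rose, 32 fell and 8 were not called after doxorubicin (1 up and 33 down adjusted over the list alone, camera adjusted p = 9.77e-15, adjusted p = 0.51 with an estimated correlation). CENPE, a kinetochore motor (-3.08 ± 0.28), BUB1B, a spindle checkpoint kinase (-3.0 ± 0.44), and CCNA2, cyclin A (-2.77 ± 0.21), had the lowest values. Of the homologous recombination and Fanconi genes, 0 of 32 rose, 21 fell and 11 were not called (0 up and 21 down adjusted over the list alone, camera adjusted p = 9.01e-07, adjusted p = 0.546 with an estimated correlation). They included RAD51D (-2.41 ± 0.38), the BLM helicase gene (-2.06 ± 0.20) and NBN (-2.03 ± 0.18). Of the apoptosis regulators, 1 of 28 rose, 8 fell and 19 were not called (1 up and 8 down adjusted over the list alone, camera adjusted p = 0.0237, adjusted p = 0.417 with an estimated correlation). The proapoptotic genes BAK1 (-2.60 ± 0.20) and BBC3 (-2.36 ± 0.30) fell. Of the p53 targets, 5 of 42 rose, 11 fell and 26 were not called (5 up and 11 down adjusted over the list alone, camera adjusted p = 0.162, adjusted p = 0.769 with an estimated correlation). Over all genes 6748 of 15888 were called, a larger share than among the p53 targets or the apoptosis regulators. PHLDA3 was at -2.73 ± 0.38 and SPATA18 at 4.12 ± 1.05, the latter going from 0 to 14 reads in U2OS and from 3 to 16 in MDA-MB231. The immediate early list went both ways, as 12 of 34 rose, 11 fell and 11 were not called (13 up and 11 down adjusted over the list alone, camera adjusted p = 0.781, adjusted p = 0.897 with an estimated correlation). ATF3 rose by 3.0 ± 0.58 and FOS by 2.49 ± 0.38, and HMOX1 (-2.51 ± 0.31) and MYC (-0.90 ± 0.31, a call lost in 9 of 19 alternatives, with adjusted p up to 0.23) fell. CDKN1A (-0.32 ± 0.51), DDIT3 (0.12 ± 0.39), IL8 (0.29 ± 0.24) and IL6 (-0.01 ± 0.31) were not called. CDKN1A lay at a log2 ratio of -1.52 in U2OS and 0.93 in MDA-MB231.

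Other genes with the highest values were SPOCK2, a matrix proteoglycan (6.30 ± 0.66), CLDN6, a tight junction protein of embryonic epithelia (6.05 ± 0.80), PYGM, muscle glycogen phosphorylase (5.76 ± 1.00), TEX14 (5.58 ± 0.66), ID2, an inhibitor of basic helix-loop-helix factors (5.08 ± 1.28), and DLL1, a Notch ligand (5.04 ± 0.80). Among the lowest values were those of TMEM177 (-5.17 ± 0.42), RFXAP, a regulator of MHC class II genes (-4.72 ± 0.63), TSPYL5 (-4.10 ± 0.27), NLRP3, an inflammasome sensor (-4.07 ± 0.64), ZNF30 (-3.98 ± 0.34), ASB13 (-3.86 ± 0.36) and KBTBD6 (-3.82 ± 0.28). Folds that rest on 3 or fewer reads in a library were those of EGR2 (3 to 4221 in MDA-MB231), CLDN6 (0 to 148 in MDA-MB231), PYGM (0 to 176 in MDA-MB231) and RFXAP (175 to 1 in U2OS). In all, 3476 genes rose and 3272 fell, 4120 of them by at least 2-fold. The count was 4058 without MDA-MB231 DMSO replicate 1, 4366 without U2OS DMSO and 1900 with no block for line. Within lines, 1679 genes were at least 2-fold higher and 2150 lower in U2OS, and 914 higher and 2100 lower in MDA-MB231. Scaling to total gene counts moved the median log2 ratio to -0.33 in U2OS and -0.22 in MDA-MB231 and the split to 855 higher and 3093 lower in U2OS and 645 higher and 2443 lower in MDA-MB231.

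Etoposide raised many immediate early and several p53 target genes in both lines and lowered mitotic and very long genes. FGFR3, a fibroblast growth factor receptor, rose by 5.04 ± 0.68 log2 units (edgeR adjusted p = 0.00555), from 2.66 to 36.4 CPM in U2OS and from 1.06 to 64.9 CPM in MDA-MB231. CDKN1A rose by 1.71 ± 0.50 (edgeR adjusted p = 0.0472), from 263 to 507 CPM in U2OS and from 150 to 996 CPM in MDA-MB231, a call lost in 12 of 20 alternatives (adjusted p up to 0.27). MDM2 was not called (0.12 ± 0.19). HAS2, a hyaluronan synthase, had the lowest value (-4.38 ± 1.17), and IL6 (-2.64 ± 0.34) and IL8 (-1.63 ± 0.25) fell.

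Of the immediate early genes, 14 of 34 rose, 3 fell and 17 were not called after etoposide (15 up and 3 down adjusted over the list alone, camera adjusted p = 0.000281, adjusted p = 0.51 with an estimated correlation). FOSB rose by 3.44 ± 0.44, FOS by 3.30 ± 0.39 and the nuclear receptor gene NR4A3 by 3.25 ± 0.58. Of the p53 targets, 9 of 42 rose, 1 fell and 32 were not called (12 up and 2 down adjusted over the list alone, camera adjusted p = 0.0105, adjusted p = 0.56 with an estimated correlation). SERTAD1 rose by 2.19 ± 0.39 and ACER2 by 1.81 ± 0.33. ATF3 (2.13 ± 0.55) and HMOX1 (1.01 ± 0.28) rose, with calls lost in 8 and 7 of 20 alternatives (adjusted p up to 0.21 and 0.53), MYC fell (-1.31 ± 0.31), and DDIT3 was not called (0.84 ± 0.38). Of the tubulin genes, 3 of 15 rose, 2 fell and 10 were not called (4 up and 3 down adjusted over the list alone, camera adjusted p = 0.315, adjusted p = 0.849 with an estimated correlation). TUBB2A was at 1.75 ± 0.21 and TUBB3 at 1.68 ± 0.25. TUBB2A has a near-identical neighbour, TUBB2B, which makes its counts uncertain. Of the integrated stress response genes that MMS raised, 3 of 33 rose, 2 fell and 28 were not called after etoposide (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.893, adjusted p = 0.977 with an estimated correlation). In the NRF2 list 5 of 31 rose, 3 fell and 23 were not called (5 up and 4 down adjusted over the list alone, camera adjusted p = 0.539, adjusted p = 0.869 with an estimated correlation). The U2OS medians of the stress response, NRF2 and tubulin lists with etoposide lay near 0 and changed sign under scaling to total counts (0.00 to 0.18, -0.05 to 0.14 and -0.06 to 0.12).

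Of the G2 and M phase genes, 0 of 41 rose, 24 fell and 17 were not called after etoposide (0 up and 31 down adjusted over the list alone, camera adjusted p = 1.28e-15, adjusted p = 0.51 with an estimated correlation). PLK1, a mitotic kinase (-2.61 ± 0.49), and CDC20, an activator of the anaphase-promoting complex (-2.04 ± 0.36), had the lowest values. Of the very long genes, 0 of 59 rose, 23 fell and 36 were not called (1 up and 27 down adjusted over the list alone, camera adjusted p = 8.85e-08, adjusted p = 0.578 with an estimated correlation). RAD51B was at -2.15 ± 0.37 and LPP at -1.83 ± 0.30. Of the epithelial markers, 0 of 16 rose, 6 fell and 10 were not called (0 up and 6 down adjusted over the list alone, camera adjusted p = 0.00049, adjusted p = 0.343 with an estimated correlation). The keratin genes KRT7 (-3.18 ± 0.23), KRT81 (-2.15 ± 0.42) and KRT18 (-1.68 ± 0.17) led it. Of the homologous recombination and Fanconi genes, 1 of 32 rose, 6 fell and 25 were not called (1 up and 6 down adjusted over the list alone, camera adjusted p = 0.00317, adjusted p = 0.686 with an estimated correlation). Their U2OS median turned from -0.05 to 0.13 under scaling to total counts. Of the ribosomal protein genes, 0 of 73 rose, 11 fell and 62 were not called (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.586 with an estimated correlation). Their median was -0.25 against 0.85 for doxorubicin. It was no lower than that of genes matched on expression in U2OS (-0.25, percentile 50 of 10000 random lists, -0.06 under scaling to total counts) and at percentile 7.41 in MDA-MB231. Of the NF-kB targets, 1 of 37 rose, 8 fell and 28 were not called (1 up and 9 down adjusted over the list alone, camera adjusted p = 0.14, adjusted p = 0.678 with an estimated correlation). PLAU, urokinase, was among them (-2.45 ± 0.42).

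The other genes with the highest values after etoposide were UNC5B, a netrin receptor (4.68 ± 0.97), the semaphorin gene SEMA6C (3.82 ± 0.32), SERPINI1, neuroserpin (3.75 ± 0.29), and HIST1H2BC (3.29 ± 0.66, a histone gene with near-identical copies). Those with the lowest were ST6GALNAC5, a sialyltransferase (-3.72 ± 0.77), KRT80 (-3.37 ± 0.33), the potassium channel gene KCNQ5 (-3.13 ± 0.45), NRG1, an ERBB receptor ligand (-3.0 ± 0.28), CCBE1 (-2.94 ± 0.42) and FAM196B (-2.88 ± 0.55). In all, 1267 genes rose and 1467 fell. The count of 2734 was 49 without MDA-MB231 DMSO replicate 1, 290 without MDA-MB231 etoposide and 381 without U2OS DMSO. It was 1718 and 1738 without the MDA-MB231 or U2OS paclitaxel library, and 0 with no block for line. Within lines, 708 genes were at least 2-fold higher and 869 lower in U2OS, and 950 higher and 1229 lower in MDA-MB231. Scaling to total counts moved the U2OS median log2 ratio to 0.16 and the U2OS split to 1096 higher and 615 lower.

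Genomic size was set against the response because of the very long gene list. Genes spanning over 300 kb had a median log2 ratio of -0.62 in U2OS and -0.63 in MDA-MB231 with etoposide, and of -1.05 and -0.51 with MMS. With paclitaxel their medians were 0.00 and 0.02, with doxorubicin -0.15 and -0.49, and between the 2 MDA-MB231 DMSO libraries 0.13. From 326 to 414 genes were in this class, depending on the pair of libraries.

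**Figure D3:**
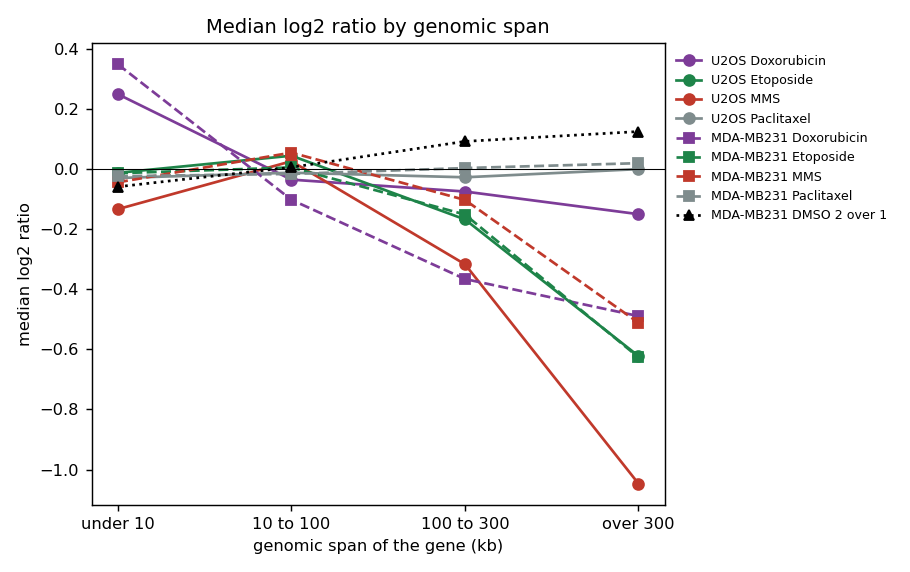
Median log2 ratio (y axis) of genes grouped by genomic span in kb (x axis), with 1 line per pair of libraries, circles for U2OS, squares for MDA-MB231 and triangles for the 2 MDA-MB231 DMSO libraries, and no error bars because each pair is 2 libraries. Over 300 kb the medians reach -1.05 for MMS in U2OS and stay at 0.00 and 0.02 for paclitaxel.

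**Figure D4:**
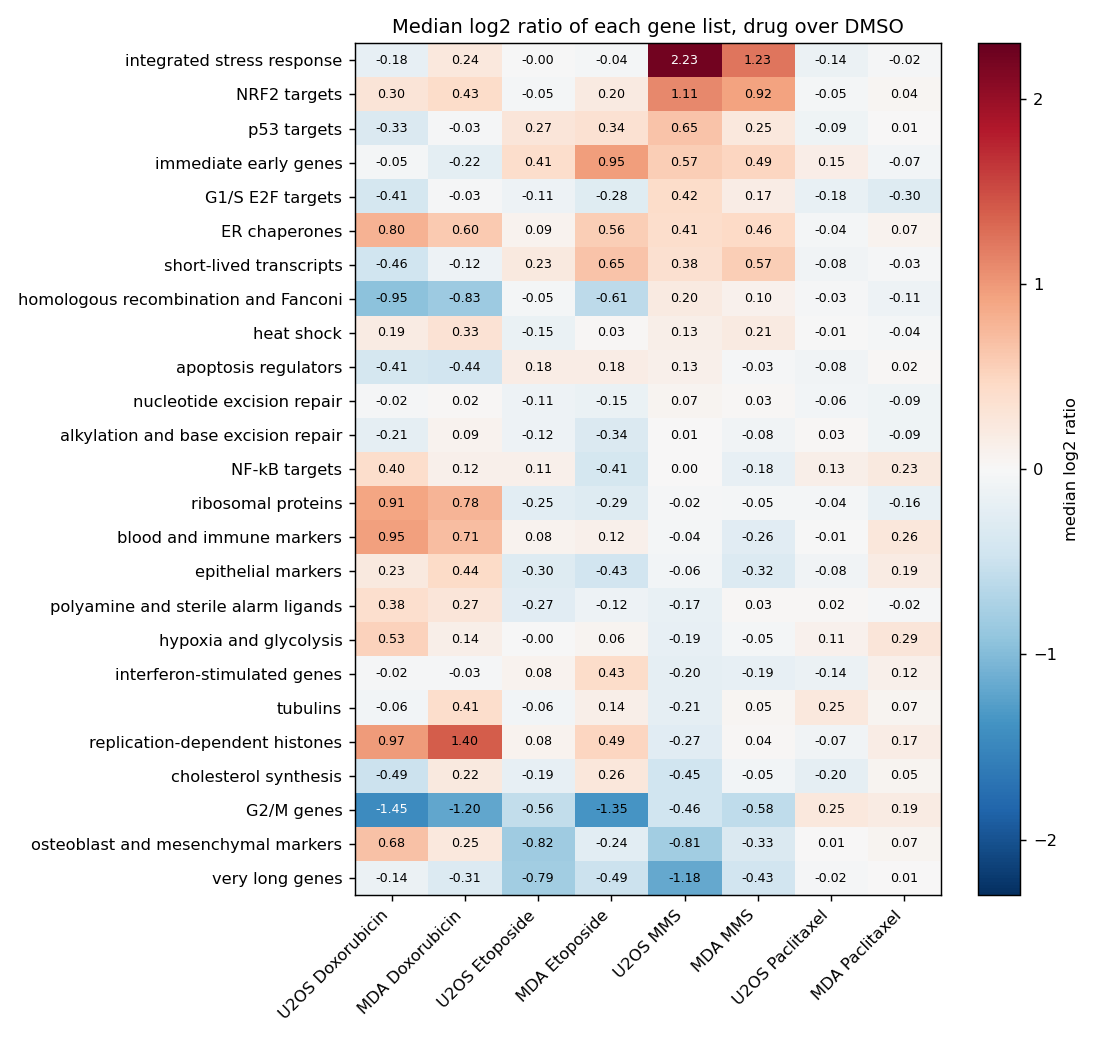
Median log2 ratio, drug over DMSO, of each of the 25 gene lists (rows) in each line and drug (columns, MDA for MDA-MB231), with the value in each cell, from 1 library per condition. Integrated stress response genes stand at 2.23 in U2OS and 1.23 in MDA-MB231 with MMS, and ribosomal protein genes at 0.91 and 0.78 with doxorubicin.

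Paclitaxel gave the fewest differences from DMSO of the 4 drugs. No gene was called for the mean change over both lines with edgeR, DESeq2 or limma-voom, and 110 of 15888 genes had an unadjusted p under 0.05 with edgeR. TUBB2A (0.26 ± 0.22), CDKN1A (-0.20 ± 0.49), ATF3 (-0.52 ± 0.56), FOS (0.64 ± 0.38) and MYC (-0.15 ± 0.30) all had adjusted p = 1. Within U2OS 9 genes were at least 2-fold higher and 1 lower, and within MDA-MB231 50 were higher and 1 lower. Against the other MDA-MB231 DMSO library 279 were higher and 119 lower, and 193 separated the 2 DMSO libraries themselves.

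In U2OS the nuclear noncoding RNA genes MALAT1 (1.36, counting interval 1.30 to 1.43) and NEAT1 (1.25, counting interval 1.22 to 1.29) were among the highest log2 ratios with paclitaxel, with PABPC1L (1.29, counting interval 1.10 to 1.56) and GOLGA8A (1.13, counting interval 0.95 to 1.36, a gene with close copies). The intervals cover counting error only. The lowest ratios among well expressed genes were those of MUC16 (-0.87), the cadherin gene FAT4 (-0.85), OASL (-0.80) and CDKN2B (-0.69), and the 1 gene at least 2-fold lower was EDN2, named after its value was seen. In MDA-MB231 the highest ratios were those of the stress cytokine gene GDF15 (2.36, counting interval 2.24 to 2.56), PTGS2, cyclooxygenase-2 (1.64, counting interval 1.54 to 1.78), SLC43A2 (1.65) and NOX5 (1.49), and the lowest those of PPARGC1B (-0.84), the noncoding gene SNHG3 (-0.82), CCNE2 (-0.81) and PDE1C (-0.80). The 1 gene at least 2-fold lower there was the microRNA host gene MIR17HG, also named after its value was seen.

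As sets, several lists shifted by small amounts with paclitaxel although none of their members was called. The G1/S list of E2F targets lay lower (median -0.29, camera adjusted p = 5.54e-29, adjusted p = 0.343 with an estimated correlation), as did ribosomal protein genes (-0.12, camera adjusted p = 1.79e-10, adjusted p = 0.51 with an estimated correlation) and integrated stress response genes (-0.20, camera adjusted p = 2.64e-05, adjusted p = 0.63 with an estimated correlation). The ribosomal protein median was -0.16 in MDA-MB231 (percentile 0 of matched random lists) and -0.04 in U2OS (percentile 52), and the stress response median -0.14 in U2OS (percentile 0) and -0.02 in MDA-MB231 (percentile 50.5), differences between single libraries that were not tested. The G2/M list lay higher (0.24, camera adjusted p = 7.99e-09, adjusted p = 0.586 with an estimated correlation). So did NF-kB targets (0.29, camera adjusted p = 4.13e-07, adjusted p = 0.343 with an estimated correlation), hypoxia and glycolysis genes (0.21, camera adjusted p = 5.79e-07, adjusted p = 0.51 with an estimated correlation) and the 15 tubulin genes (0.14, camera adjusted p = 0.00539, adjusted p = 0.546 with an estimated correlation). Within MDA-MB231 the NF-kB, hypoxia and tubulin medians were 0.23, 0.29 and 0.07 with paclitaxel, and between the 2 DMSO libraries the same medians were -0.23, -0.33 and -0.18. The count of 0 changed only when the fit held the paclitaxel libraries and their DMSO libraries alone, which called 30 genes, 26 of them higher. Among these, named after their values were seen, were TUBA1A, an alpha tubulin (0.84 ± 0.09, adjusted p = 0.0199), the mitotic kinase gene AURKA (0.54 ± 0.06, adjusted p = 0.0255) and CCNE2 (-0.72 ± 0.09, adjusted p = 0.0255), from a fit of 4 libraries with 1 residual degree of freedom.

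Setting MMS against each of the other drugs asks where the responses differ. A difference can come from either drug, each given at a single dose. It does not by itself show a response particular to alkylation. Integrated stress response genes separated MMS from each of the other 3 drugs, with 27 of 33 members higher with MMS than with etoposide, 27 higher than with doxorubicin and 27 higher than with paclitaxel, and 0 lower in each. For this list the fry adjusted p was 0.0241 against etoposide, 0.0215 against doxorubicin and 0.0232 against paclitaxel. The pseudokinase gene TRIB3 was higher with MMS than with doxorubicin by 5.95 ± 0.36 and than with etoposide by 3.51 ± 0.32. HMOX1 was higher with MMS by 6.34 ± 0.38 than with doxorubicin, by 2.82 ± 0.32 than with etoposide and by 4.31 ± 0.34 than with paclitaxel.

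Against etoposide, 752 genes were higher with MMS and 688 lower. The integrated stress response genes (32 up and 0 down adjusted over the list alone, camera adjusted p = 2.7e-38, adjusted p = 0.358 with an estimated correlation) included SLC6A9, a glycine transporter (3.21 ± 0.38). Of the NRF2 targets, 14 of 31 were higher and 0 lower (19 up and 0 down adjusted over the list alone, camera adjusted p = 1.71e-17, adjusted p = 0.21 with an estimated correlation). Highest among them were the aldo-keto reductase genes AKR1C2 (4.09 ± 0.42) and AKR1C1 (4.07 ± 0.58), which are close copies and AKR1C2 of which had 2 to 18 reads in MDA-MB231 with DMSO and MMS. IL8 (3.50 ± 0.29, 2.03 to 3.77 over 19 alternatives) and IL6 (3.11 ± 0.39, 2.06 to 3.66) were higher with MMS. Both fell with etoposide, and IL6 was not called with MMS. In MDA-MB231 these drugs had different DMSO libraries, between which IL8 itself differed. EFR3B (-3.86 ± 0.74), SBSN (-3.71 ± 0.93), HIST1H2BC (-3.48 ± 0.84), FGFR3 (-3.44 ± 0.78) and TRIM9 (-3.25 ± 0.52) were lower with MMS. Of the homologous recombination and Fanconi genes, 7 of 32 were higher and 0 lower (8 up and 0 down adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.454 with an estimated correlation). Of the interferon-stimulated genes 6 of 33 were lower and 0 higher (0 up and 10 down adjusted over the list alone, camera adjusted p = 0.00105, adjusted p = 0.386 with an estimated correlation).

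Against doxorubicin, 3235 genes were higher with MMS and 3536 lower. The integrated stress response genes (31 up and 0 down adjusted over the list alone, camera adjusted p = 4.75e-18, adjusted p = 0.386 with an estimated correlation) included ATF4, the transcription factor at the centre of that response (3.91 ± 0.18), and CHAC1 (5.74 ± 0.43). FUT1, a fucosyltransferase (6.36 ± 1.14), and OSGIN1 (6.22 ± 0.53) were also higher, and EGR2 (-6.14 ± 1.20), MYCL1 (-5.79 ± 1.01), LGR5 (-4.93 ± 0.62), the protease inhibitor gene SERPINA3 (-4.92 ± 0.85) and ID2 (-4.85 ± 1.65) were lower. Among them 3 or fewer reads stood behind FUT1 (11 to 3 in U2OS with DMSO and doxorubicin), and, in MDA-MB231 with DMSO and MMS, EGR2 (1 to 7), LGR5 (7 to 2) and SERPINA3 (5 to 2). Of the p53 targets, 20 of 42 were higher and 3 lower (20 up and 5 down adjusted over the list alone, camera adjusted p = 0.000397, adjusted p = 0.39 with an estimated correlation). MDM2, which rose with MMS and fell with doxorubicin, was higher by 3.42 ± 0.23 and GADD45A by 3.76 ± 0.36. The NRF2 targets went both ways, with 14 of 31 higher and 8 lower (14 up and 8 down adjusted over the list alone, camera adjusted p = 0.000397, adjusted p = 0.39 with an estimated correlation). Of the homologous recombination and Fanconi genes, 21 of 32 were higher and 0 lower (21 up and 0 down adjusted over the list alone, camera adjusted p = 9.5e-07, adjusted p = 0.403 with an estimated correlation), including BRCA2 (2.3 ± 0.20). Of the ribosomal protein genes, 65 of 73 were lower and 0 higher (0 up and 66 down adjusted over the list alone, camera adjusted p = 8.4e-15, adjusted p = 0.386 with an estimated correlation). For the recombination and ribosomal protein lists, doxorubicin made the larger part of the gap. Recombination list medians were 0.20 in U2OS and 0.10 in MDA-MB231 with MMS, and -0.95 and -0.83 with doxorubicin. Ribosomal protein medians were -0.02 and -0.05 with MMS, and 0.91 and 0.78 with doxorubicin.

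Against paclitaxel, 542 genes were higher with MMS and 611 lower. Those with the highest values were ATF3 (5.17 ± 0.66), CHAC1 (4.51 ± 0.41), HMOX1, CTH (4.09 ± 0.64) and ADM2, an adrenomedullin-family peptide (3.92 ± 0.37), and those among the lowest PDE4B, a cyclic AMP phosphodiesterase (-4.53 ± 0.56), TRIB2 (-4.23 ± 0.47), ZNF608 (-3.71 ± 0.54) and NOG (-3.41 ± 0.50). The integrated stress response list gave 31 up and 0 down adjusted over the list alone, camera adjusted p = 1.14e-45, adjusted p = 0.338 with an estimated correlation. Of the NRF2 targets 14 of 31 were higher and 0 lower (18 up and 0 down adjusted over the list alone, camera adjusted p = 4.23e-22, adjusted p = 0.21 with an estimated correlation). Of the G2/M genes, 17 of 41 were lower and 0 higher (0 up and 27 down adjusted over the list alone, camera adjusted p = 2.51e-14, adjusted p = 0.39 with an estimated correlation).

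Each of these contrasts with MMS leaned on single libraries. Without the U2OS MMS library, 2 genes differed from etoposide (the chemokine genes CXCL2 and CXCL3, named after their values were seen), 0 from paclitaxel and 1884 from doxorubicin. The count against etoposide lay from 439 (without MDA-MB231 etoposide) to 2369 (without U2OS doxorubicin) when any other library was left out. It was 454 without MDA-MB231 DMSO replicate 1, 626 without U2OS etoposide, 747 and 750 without the MDA-MB231 or U2OS paclitaxel library, and 801 without U2OS DMSO. The MMS effect came from U2OS alone without MDA-MB231 MMS or MDA-MB231 DMSO replicate 2, and from MDA-MB231 alone without U2OS MMS. Such fits do not check both lines. The count against etoposide was 2328 without MDA-MB231 doxorubicin. Against paclitaxel it was 19 without MDA-MB231 paclitaxel, 24 without U2OS paclitaxel, 479 without MDA-MB231 DMSO replicate 1, 627 without U2OS DMSO, and 1853 and 1874 without the MDA-MB231 or U2OS doxorubicin library. With no block for line the counts were 0 against etoposide, 0 against paclitaxel and 2062 against doxorubicin, and with DESeq2 they were 2796 against etoposide and 2531 against paclitaxel.

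Whether the lines responded differently was tested with 1 term for treated U2OS cells, averaged over the 4 drugs. No gene was called with edgeR or limma-voom, 204 had an unadjusted p under 0.05 with edgeR, and DESeq2 called 2, PABPC1L (1.70) and PTGS2 (-1.77), log2 differences of U2OS from MDA-MB231, named after their values were seen. Leaving out the paclitaxel library of MDA-MB231 or of U2OS gave 1 call, the tissue factor gene F3 (3.03 and 3.04). Among the lists, cholesterol synthesis genes lay lower in treated U2OS than in treated MDA-MB231 (median -0.37, camera adjusted p = 7.03e-07, adjusted p = 0.877 with an estimated correlation) and integrated stress response genes higher (0.39, camera adjusted p = 0.00337, adjusted p = 0.877 with an estimated correlation). MMS carried the latter, with a median line difference of 1.11 (0.73 with the other MDA-MB231 DMSO library) against 0.14 for etoposide, -0.13 for doxorubicin and -0.06 for paclitaxel. Replication-dependent histones (-0.97, camera adjusted p = 0.0007) and very long genes (-0.29, camera adjusted p = 0.0007) lay lower in treated U2OS. The G1/S list (0.14, camera adjusted p = 0.0227) and ribosomal protein genes (0.06, camera adjusted p = 0.0232) lay higher, each of these 4 with adjusted p = 0.877 with an estimated correlation. No member of any list was called over all genes, and 1 NF-kB target was lower when adjusted over the list alone. For this term the fry adjusted p was 0.989 for every list.

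Drug by drug, line differences can only be described, since each rests on 4 libraries. With MMS the integrated stress response list had a median log2 ratio of 2.23 in U2OS and 1.23 in MDA-MB231. Gene by gene, the U2OS ratio exceeded that of MDA-MB231 by a median of 1.11, above all of 10000 random lists matched on expression. With the other MDA-MB231 DMSO library the median was 0.73 (bootstrap interval over genes 0.50 to 1.04). That interval treats the list genes as independent and covers no variation between libraries or cultures. For p53 targets the medians were 0.65 and 0.25 with MMS, 0.27 and 0.34 with etoposide and -0.33 and -0.03 with doxorubicin. CDKN1A went from 263 to 767 CPM in U2OS and from 104 to 302 CPM in MDA-MB231 with MMS. G2/M genes had a median of -0.56 in U2OS and -1.35 in MDA-MB231 with etoposide. The genes with the highest MMS ratios in U2OS included RAB39B, a small GTPase (5.10, with 0 reads in both MDA-MB231 libraries), and the lowest included HMGA2, a chromatin architectural factor (-4.62, against -1.07), and AMIGO2, an adhesion protein (-4.41, against 0.00). With etoposide the neurotrophin receptor gene NGFR had the highest ratio in U2OS (4.87, against -0.29 in MDA-MB231), and with doxorubicin CYR61, a matrix signalling protein, had the lowest in MDA-MB231 (-4.46, against -2.37 in U2OS).

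The same drug gave similar profiles in both lines, apart from paclitaxel. Across genes, which are not independent replicates, the U2OS and MDA-MB231 log2 ratios had a Pearson r of 0.82 for doxorubicin (10525 genes), 0.74 for etoposide (10418), 0.72 for MMS (10241) and 0.29 for paclitaxel (10167). The lines share no control library. Among 16 pairs of drugs across lines, the highest r between different drugs was 0.43, for MMS in U2OS with etoposide in MDA-MB231, and the reverse pairing gave 0.29. For doxorubicin, 603 genes were at least 2-fold higher in both lines where independent lists would share 105, and 1310 were lower in both where they would share 362. For MMS 186 were higher in both against 18.0 and 220 lower against 28.0, and for etoposide 325 against 46.6 and 430 against 68.1.

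**Figure D5:**
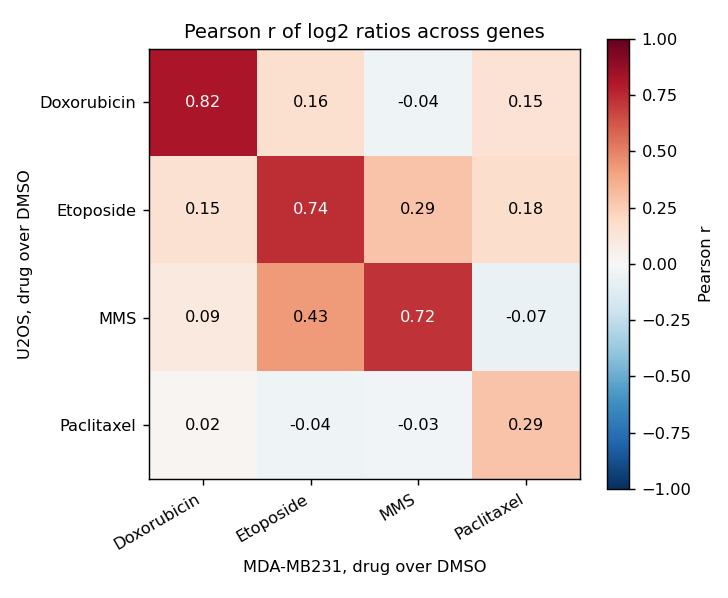
Pearson r across genes between the log2 ratios (drug over DMSO) of U2OS (rows) and of MDA-MB231 (columns), with the value in each cell. The same-drug values on the diagonal are 0.82, 0.74, 0.72 and 0.29.

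Without any drug between them, the 2 MDA-MB231 DMSO libraries differed by at least 2-fold in 193 genes, 89 higher and 104 lower in replicate 2. The melanoma antigen genes MAGEA12 (from 0.12 to 22.2 CPM, 3 reads against 355) and MAGEA6 (from 0.59 to 21.9 CPM), which are close copies, and SERPINB2 (from 1.53 to 32.5 CPM) were higher in replicate 2, and CALB2, calretinin (from 57.2 to 13.5 CPM), was lower. Hypoxia and glycolysis genes had a median log2 ratio of -0.33 and NF-kB targets of -0.23 between these 2 libraries, both at percentile 0 of 10000 matched random lists, and integrated stress response genes had 0.23, at percentile 99.99. IL8 went from 1212 to 549 CPM between replicates 1 and 2.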

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

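No test was run for the values in this part. HAS2 and HIST2H2BE were picked by their values, as named genes at least 2-fold apart in opposite directions in the lines. The read shares were picked because they exceeded the difference between the MDA-MB231 DMSO libraries. HAS2, a hyaluronan synthase gene, moved in opposite directions with MMS, with a log2 ratio of -4.14 in U2OS and 1.14 in MDA-MB231, a difference of -5.28 that was not tested. HIST2H2BE, a histone gene with near-identical copies, had -1.09 in U2OS (counting interval -1.25 to -0.96) with MMS. In MDA-MB231 it had 1.41 (counting interval 1.06 to 2.25), a difference of -2.50 that was not tested.

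The share of reads aligned to several places, which lies outside the gene counts, was higher than in the matching DMSO library by 4.44 percentage points in MDA-MB231 with doxorubicin, by 4.75 in U2OS with doxorubicin and by 0.478 in MDA-MB231 with MMS, where the 2 MDA-MB231 DMSO libraries differed by 0.461. The share of reads outside annotated genes was higher in U2OS than in its DMSO library by 1.96 percentage points with doxorubicin, 1.12 with etoposide and 1.53 with MMS, where the 2 MDA-MB231 DMSO libraries differed by 1.00.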

How the results depend on the processing

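The fit without both doxorubicin libraries was chosen after seeing the data, and all other alternatives before. No named gene was called in the opposite direction. Scaling to total counts turned the etoposide split from 708 higher and 869 lower to 1096 and 615 in U2OS and from 950 and 1229 to 1149 and 1060 in MDA-MB231, and 9 of the 25 U2OS etoposide list medians changed sign. Among the alternatives for named genes, 2262 values kept both their direction and their side of the threshold, 321 lost the call in the same direction and 37 gained it. A further 58 changed sign without being called in either fit. Among the alternatives for gene lists 40 calls were lost, each with an estimated correlation, and 21 medians moved. The calls lost most often were those of CDKN1A with etoposide and with MMS (12 of 20 alternatives each), of HAS2 with etoposide (11 of 20) and of HIST1H2BC for MMS against etoposide (11 of 19). Further calls often lost were those of SBSN (10 of 19) and FGFR3 (8 of 19) for MMS against etoposide and of ID2 for MMS against doxorubicin (10 of 18). The causes of these changes and of those below were not tested.

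With no replicate block the counts were 1900 for doxorubicin, 0 for etoposide, 0 for MMS, and 2062, 0 and 0 for MMS against doxorubicin, etoposide and paclitaxel; the lines' baselines then enter the residual spread. DESeq2 called 2903 genes for MMS, 2796 for MMS against etoposide, 2531 against paclitaxel and 2 for the line term. A block for cell line alone gave 2434 for MMS against etoposide. With only a drug's own libraries and their DMSO libraries, MMS had 641 and paclitaxel 30. Without both doxorubicin libraries, MMS against etoposide had 2310 and against paclitaxel 1814.

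Leaving out each library in turn gave 4058 to 7057 genes for doxorubicin, 49 to 3709 for etoposide, 0 to 2537 for MMS, 0 to 0 for paclitaxel, 1884 to 6884 for MMS against doxorubicin, 2 to 2369 against etoposide, 0 to 1874 against paclitaxel and 0 to 1 for the line term, which could not be fitted without the U2OS DMSO library. Where a drug was left with 1 library, that library was assumed to vary like the others. Its response then came from 1 line, as did that of MMS without MDA-MB231 DMSO replicate 2. At least 2-fold apart with paclitaxel were 25 genes in U2OS at a CPM minimum of 1 and 5 with 2 added to CPM, and in MDA-MB231 96, 25 and, against the other DMSO library, 398. The DMSO libraries differed in 383 genes at a CPM minimum of 1. Libraries held 16774156 to 31588683 counts, so counting error is largest for genes of few CPM, and what else limits the calls was not tested.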

Other observations

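In the weighing of 3 patterns in this part, the tests on genes over 300 kb, the test of slower transcription, the test of library scaling, the test of an overall smaller MDA-MB231 response and the comparisons with doxorubicin and with the short-lived list were chosen only after the result was seen. The intervals given for these patterns resampled genes of single libraries, so they cover no variation between libraries or cultures. Gene lists that the comparisons above leave out gave mixed results. Of the NF-kB targets, 3 of 37 rose, 6 fell and 28 were not called after MMS (7 up and 9 down adjusted over the list alone, camera adjusted p = 0.634, adjusted p = 0.876 with an estimated correlation). The monocyte chemokine gene CCL2 fell (-4.49 ± 0.60, 65 to 2 reads in U2OS) and the neutrophil chemokine gene CXCL2 rose (1.64 ± 0.34). After doxorubicin 10 of 37 rose, 5 fell and 22 were not called (10 up and 5 down adjusted over the list alone, camera adjusted p = 0.514, adjusted p = 0.869 with an estimated correlation). CXCL10, an interferon-induced chemokine, was at 3.91 ± 0.87 (0 to 55 reads in U2OS) and the inhibitor gene NFKBIA at -2.07 ± 0.34. Of the interferon-stimulated genes, 6 of 33 rose, 0 fell and 27 were not called after etoposide (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.0506, adjusted p = 0.546 with an estimated correlation), IRF7 being at 2.68 ± 0.33. Of the cholesterol synthesis genes, 0 of 25 rose, 3 fell and 22 were not called after MMS (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.0784, adjusted p = 0.869 with an estimated correlation).

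Of the alkylation and base excision repair genes, 1 of 27 rose, 2 fell and 24 were not called after MMS (1 up and 2 down adjusted over the list alone, camera adjusted p = 0.875, adjusted p = 0.961 with an estimated correlation), a share of calls near that of all genes (1651 of 15888). The glycosylase gene MBD4 was at 0.86 ± 0.19 and the scaffold gene XRCC1 at -0.78 ± 0.20. Of the nucleotide excision repair genes, 2 of 26 rose, 0 fell and 24 were not called (2 up and 0 down adjusted over the list alone, camera adjusted p = 0.781, adjusted p = 0.876 with an estimated correlation), the damage sensor XPC being at 0.78 ± 0.19. In the polyamine and alarm ligand list 1 of 12 rose, 1 fell and 10 were not called (3 up and 2 down adjusted over the list alone, camera adjusted p = 0.687, adjusted p = 0.873 with an estimated correlation). SMOX, spermine oxidase, was at 1.17 ± 0.26 and SMS, spermine synthase, at -0.72 ± 0.19. Of the hypoxia and glycolysis genes, 2 of 27 rose, 3 fell and 22 were not called (2 up and 3 down adjusted over the list alone, camera adjusted p = 0.552, adjusted p = 0.884 with an estimated correlation). ADM, adrenomedullin, was at 1.61 ± 0.35 and the glucose transporter gene SLC2A1 at -0.95 ± 0.14. Of the epithelial markers, 1 of 16 rose, 2 fell and 13 were not called (2 up and 2 down adjusted over the list alone, camera adjusted p = 0.687, adjusted p = 0.876 with an estimated correlation), with the splicing regulator ESRP1 at 5.29 ± 0.94 (0 to 116 reads in U2OS, 1 to 13 in MDA-MB231).

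Genes with long genomic spans were lower after etoposide and MMS in both lines. Across genes, the weakest Spearman rho of span with log2 ratio among the 4 library pairs was -0.157 within bins of transcript length and -0.125 within bins of GC content (0.054 and 0.172 between the 2 DMSO libraries), and without bins rho was -0.158 to -0.111 in these pairs and 0.199 between the DMSO libraries. This left transcript length, GC content and slower transcription undecided, and genes over 300 kb were examined next for that reason. Their median difference from shorter genes of like length and expression was -0.52 or lower, and of like GC content -0.58 or lower, in all 4 pairs, while in the paclitaxel and DMSO pairs the values farthest from 0 were 0.066 length-matched and 0.14 GC-matched, which argues against length and GC content for these genes. Slower transcription through long genes under DNA damage stays open as a hypothesis found and tested on the same data, since with doxorubicin, which also damages DNA, the U2OS and MDA-MB231 values were -0.08 (-0.17 to 0.05) and -0.11 (-0.22 to 0.01) length-matched and -0.07 (-0.19 to 0.04) and -0.23 (-0.33 to -0.12) GC-matched.

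Ribosomal protein mRNAs were higher after doxorubicin. Scaling to total counts left their median at 0.63 or more in both lines, against 0.91 in U2OS and 0.78 in MDA-MB231 with TMM. The choice between these 2 scalings therefore did not account for all of the shift. Both scalings are relative, so they cannot tell a gain of these mRNAs from a loss of other mRNA. Ribosomal protein genes differed from other genes of like transcript length and expression by 0.19 (-0.027 to 0.31) in U2OS and 0.15 (0.035 to 0.21) in MDA-MB231. The U2OS interval does not exclude no difference. These values are small beside 0.91 and 0.78, so a gain of short abundant transcripts in general stays open. Zinc finger genes, a class known for short-lived mRNAs, differed from genes of like expression by a median of -0.66 or lower in both lines. A loss of short-lived relative to stable mRNAs stays open. The short-lived transcript list lay at percentile 1.39 of matched random lists in U2OS but at 40.4 in MDA-MB231. That list cannot decide the question, as 21 of its 35 members also belong to other lists and its median mixes opposite responses. With doxorubicin 6 members were at least 2-fold higher and 15 lower in U2OS, and 9 higher and 11 lower in MDA-MB231.

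Integrated stress response genes had higher medians in U2OS than in MDA-MB231 with MMS. Against the other MDA-MB231 DMSO library the median difference was 0.73 (bootstrap interval 0.50 to 1.04) instead of 1.11, so the control moves its size without deciding it. The ratio of the MDA-MB231 to the U2OS median differed between NRF2 targets and stress response genes by 0.279 (-0.235 to 0.708), so an overall smaller MDA-MB231 response stays open. The title set of the MDA-MB231 MMS library and its line cannot be told apart, and the other differences between the lines were not tested.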
